A study of Mus musculus with 4 samples.

How the data were processed

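Gene expression was measured in RNA from the whole small intestine of female mice at 8 weeks of age. Wild-type (WT) mice, labelled C57BL/6, and IL-17RA-deficient mice were uninfected or had received Giardia muris by oral gavage 2 weeks earlier. Per the labels, equal amounts of RNA from 6 mice were pooled for each group, and 150 ng of RNA was labelled with Cy3. The 4 pools were hybridised to 4 arrays of Agilent design 014868. They lay on 1 slide and were read in 1 scan, so the position of an array and its group cannot be told apart.

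Spot signals were in intensity per the file headers, as the authors' scanner software, Agilent Feature Extraction 9.5.3.1 with protocol GE1-v5_95_Feb07, wrote them. The processed signal had the background subtracted and spatial trends removed within each array, with no scaling between arrays. The flags for signal well above background, saturation and outlier spots were taken from the same software. A second deposited table gave intensity for each spot on a linear scale. Its medians were 175.3 for WT uninfected, 177.3 for WT infected, 175.0 for the array labelled IL-17RA-deficient uninfected and 176.8 for the array labelled IL-17RA-deficient infected. Its values followed the raw spot medians with rank correlations of at least 0.9995, and how the authors scaled it between arrays is not given in the sources used here.

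Of 45018 spots per array, 1486 positive and 153 negative control spots were left out, and 43379 were used. Outlier spots, 83, 72, 63 and 68 on the arrays in the order above, were left out, and 0 spots were saturated. Log2 processed signals were scaled by subtracting each array's 75th percentile, and spots of the same probe were averaged. The 41174 probes comprised 40929 printed once and 245 printed 10 times. Names came from a reference gene table (assembly GRCm38.p6), used for names only, for 24367 probes and from the array annotation for 16807. Together they gave 28464 gene names, of which 18216 were symbols, and 8641 genes had 2 or more probes. Each gene was given the value of its probe with the highest mean over the 4 arrays. Probe positions are from the array annotation on mm8.

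Differences are between 2 single arrays, so there is no test and no p-value. A difference counted as measured where the probe was well above background on both arrays, and counts are of genes at least 2-fold higher or lower. Where a gene was well above background on 1 array only, a bound was built by setting its other array to the lowest signal well above background on that array, or to the gene's own value if higher. Bounds were counted apart and are written as at least so many fold.

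Before the data were examined, 39 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. A list's value is the median log2 difference of its members well above background on at least 1 of the 2 arrays, with dim sides at their bound, and 3 such members were needed. Its percentile is its place among 10000 random lists of the same size, matched on mean expression in 20 bins, and the central 95% of random lists served as a reference range. These percentiles describe the arrays and do not test a difference between mice. Some genes are in more than 1 list. The rule named the 12 genes with a symbol highest and lowest in each comparison, of which the first 8 on each side are given for the infection comparisons and the first 5 for the genotype comparisons, with the range of the others. It also named up to 5 bounds on each side, Il17ra and any list member. For the difference between the infection responses it named 12 genes on each side, with all 4 arrays well above background. A gene whose probes disagreed in sign was given with both values. Some genes that the rule selects are not reported here.

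Measurement error was taken from the probes printed 10 times on each array. The calculation was run on simulated data with the noise of these probes. Of genes simulated at log2 1.5, 2, 3 or -2, 100% counted as at least 2-fold, as did 0 unchanged genes. That noise is small beside the 2-fold cut, so this outcome was set in advance and checks the calculation only. The simulation held no spread between pools and says nothing of how many 2-fold differences are false. For the lists, the measured WT infection differences were used instead. Of random lists, 5.0% fell outside the central 95% range, which holds by construction because the reference lists come from the same genes. Of lists shifted by log2 0.5, 100% were above it. The agreement of the infection responses was described by Pearson's r and Spearman's rho across genes, which are not independent replicates.

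The alternatives were normexp background correction with offset 50, quantile scaling, scaling to the array median, cyclic loess, the mean over all probes of a gene, no background filter, well above background on all 4 arrays, the brighter part of the probes above background, the authors' scaled table, and thresholds of 1.5-fold and 3-fold. Lists were also summarised by their mean and with members well above background on both arrays only. List values without the floor on dim signals were added after seeing the data. Leaving out a replicate was impossible with 1 array per group. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.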

Results

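The 4 arrays covered the WT uninfected, WT infected, IL-17RA-deficient uninfected and IL-17RA-deficient infected groups, with 1 array per group and no replicates. Giardia muris is a protozoan parasite of the mouse small intestine, and IL-17RA is a receptor subunit shared by IL-17A, IL-17F, IL-17C and IL-25. In that order, 68.8%, 69.0%, 69.2% and 68.5% of the 43379 spots were well above background, giving 19335, 19428, 19394 and 19298 genes. The 75th percentile of signal was 1204, 1090, 1294 and 1225 against negative control medians of 3.84, 3.45, 3.97 and 4.09. The SD of a log2 difference between repeated spots was 0.11, 0.09, 0.11 and 0.10 in the WT infection, deficient infection, uninfected genotype and infected genotype comparisons. Among the dimmest of these spots it was 0.17, 0.15, 0.18 and 0.15, and among the brightest 0.04 to 0.06. That error covers the measurement only, since the number of arrays leaves the spread between mice unknown.

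Il17ra, the targeted gene, had a higher signal on the arrays labelled IL-17RA-deficient than on the WT arrays. Its brighter probe, at 120448481 to 120448540 on chromosome 6 (mm8), read 372 and 340 on the WT uninfected and infected arrays and 1144 and 1092 on the arrays labelled IL-17RA-deficient. Scaled by the 75th percentile, these signals are 2.86-fold higher, a log2 difference of 1.52, in both genotype comparisons. The other probe, at 120448344 to 120448403, gave log2 differences of 1.56 and 1.48. The direction goes against the labels. Whether these probes lie in the deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing. Directions between genotypes therefore refer to the labels of the arrays.

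The WT infection comparison asks which small intestinal genes differ in WT mice 2 weeks after infection. By list median, IL-17 response genes, tuft cell genes and eosinophil genes were higher on the infected array. Genes of drug metabolism, bile acid handling and the circadian clock were lower by list median. Of 18939 measured genes, 396 were at least 2-fold higher and 293 at least 2-fold lower, and bounds added 85 and 53. The phospholipase gene Pla2g4c was 94.9-fold higher and Retnlb, which encodes a secreted goblet cell protein, was 88.5-fold higher. The fucosyltransferase gene Fut2 was 37.7-fold higher, with its other probe at a log2 difference of 2.23.

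The serum amyloid genes Saa2, Saa1 and Saa3 were 27.8-fold, 22.4-fold and 17.6-fold higher, and their sequences are similar enough for probes to share signal. Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase DUOX2, was 17.4-fold higher, and Gml2 was 16.2-fold higher. The next 4 genes had log2 differences of 3.31 to 4.01. The IL-17 response list had a median of 1.56 (percentile 100), with 11 of 21 members at least 2-fold higher and 0 lower. Among them were S100a9 at 2.61, Duox2 at 1.75 and Zc3h12a at 1.56, while Reg3g was at 0.32 and the IgA transporter gene Pigr at 0.42. The list of IL-17 and Th17 cytokines and receptors was at 0.26 (percentile 99.2), with Il22 at 1.55 and Il17a at least 4.62-fold higher. Its median was -0.22 among brighter probes.

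Genes of type 2 immunity were higher together. The type 2 cytokine and tuft cell list had a median of 1.5 (percentile 100), with 10 of 18 members at least 2-fold higher. Tuft cells are chemosensory epithelial cells, and their genes Gfi1b, Alox5, Trpm5, Avil and Dclk1 were at 2.36, 2.15, 2.10, 2.10 and 1.84. Il25, a cytokine made by tuft cells, was at 1.54 and Il4 at 1.73, while Il13 was at 0.23. The eosinophil list was at 1.52 (percentile 100), with 6 of 10 members at least 2-fold higher, including Siglecf at 2.21, Ccr3 at 1.54 and Ear3 at 1.63. The mast cell list was at 0.80 (percentile 100), with 3 of 10 members at least 2-fold higher, among them the mucosal mast cell protease gene Mcpt1 at 1.05. Paneth cell genes other than alpha-defensins were at 0.62 (percentile 100), with Pnliprp2 at 2.17, Gpx2 at 1.37 and Clps at 1.35 but Lyz1 at -0.08. Goblet cell genes were at 0.24 (percentile 100), with Muc4 at 1.5 and Muc2 at 0.12.

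At the lower end, Cubn, the receptor for intrinsic factor and vitamin B12, was 28.1-fold lower, and Bco1, which splits beta-carotene, was 24.9-fold lower. Also among the 8 lowest were Hsd3b2 at -3.33, Olfr165 at -3.24, Actc1 at -3.02, Acp6 at -3.00 and Cyp3a41a at -2.83. The next 4 genes were at -2.80 to -2.64. The cryptdin-related gene Defcr-rs2 was 2139-fold lower, a rough value because its signal on the infected array was near background. Defcr-rs10 was at least 2318-fold lower, whereas the alpha-defensin list as a whole was at 0.04 (percentile 74.6). Xenobiotic metabolism genes had a median of -0.86 (percentile 0), with 14 of 32 members at least 2-fold lower, including Cyp3a11 at -2.80, Ugt2b5 at -2.15 and Cyp2b10 at -2.01. Bile acid handling genes were at -0.66 (percentile 0), with 4 of 12 members at least 2-fold lower and 1 higher. Fabp6 was at -1.95 and Abcb1a at -2.0 against Fgf15 at 2.51. Brush border hydrolases and nutrient transporters were at -0.34 and lipid absorption genes at -0.24 (percentile 0 for both), with Slc6a20a at -2.04 and Abca1 at -1.73. Cholesterol biosynthesis genes were at 0.55 (percentile 100), with Sqle at 1.13 and Cyp51 at 1.02.

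Some other cell type lists and the time-of-day genes had medians outside the range of random lists on these WT arrays too. Circadian clock genes had a median of -0.83 (percentile 0), with 6 of 19 members at least 2-fold lower and 2 higher, and Dbp was at -2.46, Per2 at -1.93 and Arntl at 1.03. The time of day at which tissue was taken is not given in the sources used here. T cell and cytotoxic lymphocyte genes were at -0.55 (percentile 0), with Cd160 at -1.15 and Gzmb at -1.05. Plasma cell and IgA genes were at 0.51 (percentile 100), and B cell and follicle genes at 0.26 (percentile 99.7), the latter at -0.08 among brighter probes. Type I interferon-stimulated genes were at 0.48 (percentile 100), with Ifi44 at 1.58 and Usp18 at 1.48. Smooth muscle genes were at 0.23, macrophage and neutrophil genes at 0.22 and neighbours of Il17ra at 0.18. Adipose genes were at -0.34, immediate early and heat shock genes at -0.36, enteroendocrine genes at -0.21 and proliferation genes at -0.12. Proximal and distal small intestine genes were at -0.18 and -0.17, and enteric neuron and glia genes at -0.32, or 0.03 among brighter probes. The smooth muscle, adipose, enteroendocrine, proliferation and enteric neuron lists held 0 members at least 2-fold higher or lower.

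Inside the range of the central 95% of random lists were blood genes at 0.23, housekeeping genes at 0.08, complement and lectin genes at 0.05 and pancreas acinar genes at 0.01. Ribosomal protein genes at -0.03, interferon-gamma response genes at -0.04, PPAR-alpha target genes at -0.06, liver genes at -0.07 and MHC class II genes at -0.16 were inside it too. Unfolded protein response genes were also inside it, at -0.01. Of the 38 lists with enough members, 27 were outside that range, against 1.9 expected for lists of unrelated genes. Members of a list can vary together and some are shared, so this count does not test an effect of infection. The list of genes that differ between mouse strains had only Nnt and Pla2g2a measured, at -0.93 and 0.64, and was not scored. The largest bounds included Ppef1 and Myot at least 19.9-fold and 10.1-fold higher and Hsd3b3 at least 10.7-fold lower. The total of 689 genes was 407 with normexp background correction, 418 on the authors' scaled table, 265 among brighter probes and 1677 with no background filter.

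**Figure D1:**
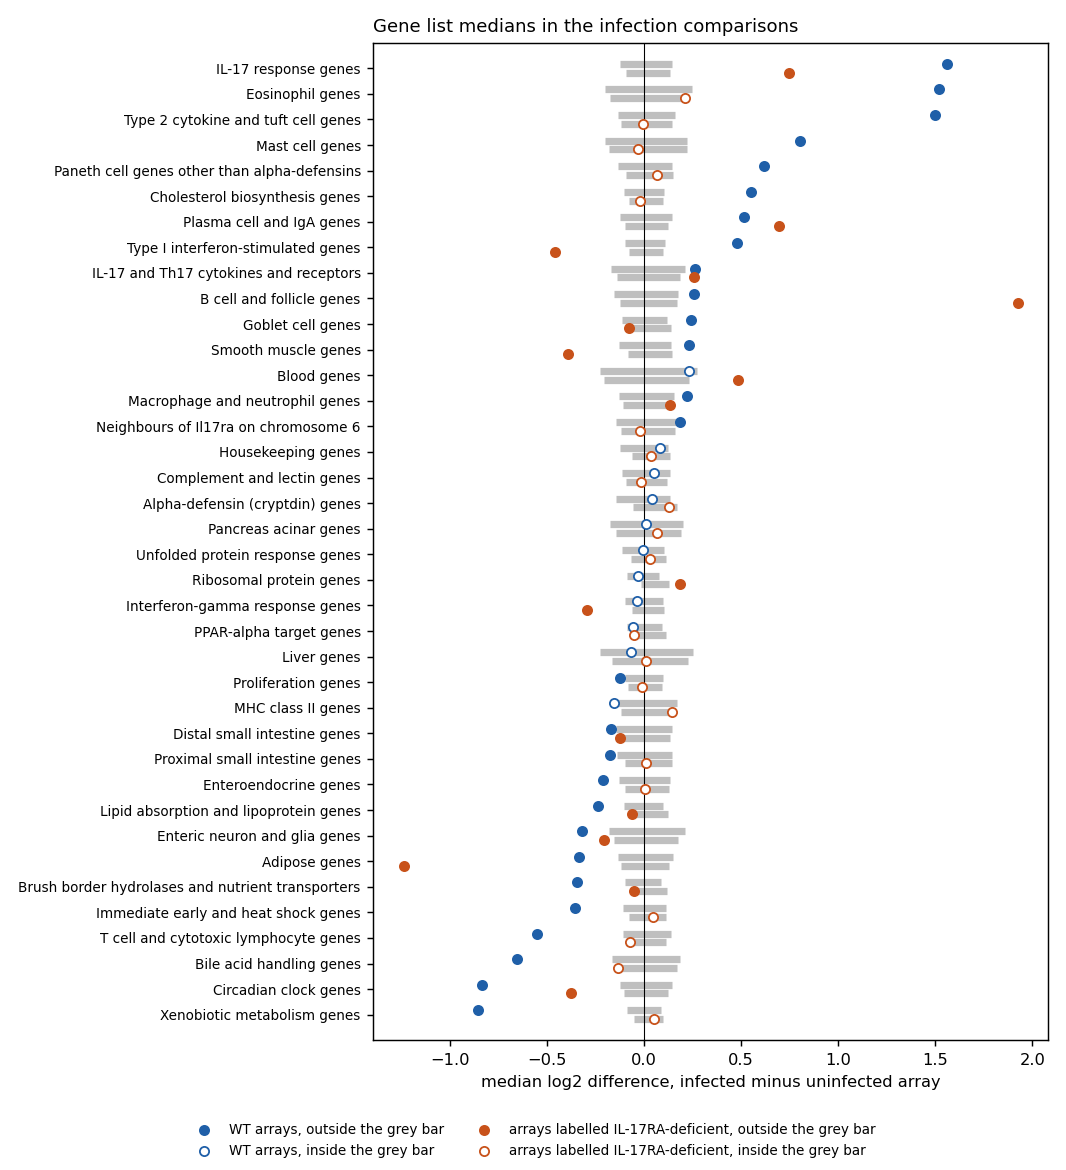
Median log2 difference between infected and uninfected arrays for the 38 scored gene lists, on the WT arrays (blue) and the arrays labelled IL-17RA-deficient (orange), with grey bars for the central 95% of 10000 matched random lists. The type 2 cytokine and tuft cell list is at 1.5 on the WT arrays and inside the bar on the others, and the B cell and follicle list is at 0.26 and 1.93.

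The deficient infection comparison asks the same question on the arrays labelled IL-17RA-deficient. B cell and lymphoid follicle genes and Il22 were higher on the infected array, tuft cell and eosinophil genes were near the uninfected level, and adipose genes were lower. Of 18887 measured genes, 287 were at least 2-fold higher and 113 at least 2-fold lower, with bounds for 74 and 35 more. The B cell surface gene Ms4a1 was 26-fold higher, with its other probe at a log2 difference of 4.60. The B cell homing receptor gene Cxcr5 was 20.5-fold higher, and the IgM receptor gene Fcmr was 16.7-fold higher.

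B cell and follicle genes had a median of 1.93 (percentile 100), with 18 of 20 members at least 2-fold higher and 0 lower. They included Bank1 at 2.44, Cd79b at 2.34 and Pax5 at least 21.2-fold higher. Tnfrsf13c, the receptor for BAFF, was 11.8-fold higher. Plasma cell and IgA genes were at 0.70 (percentile 100), with 6 of 16 members at least 2-fold higher, such as Pou2af1 at 2.01 and Mzb1 at 1.41. Glycam1, a gene of high endothelial venules, was at least 11-fold higher, and Cd180 at least 7.02-fold higher. Beside these, blood genes were at 0.48 (percentile 100), with the globin gene Hba-a1 at 1.34 and Alas2 at 1.33, and ribosomal protein genes were at 0.19. T cell and cytotoxic lymphocyte genes were at -0.07.

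Il22, an epithelial-acting cytokine gene, was 16.1-fold higher, and Cyp1a1, a target of the aryl hydrocarbon receptor, was 15.4-fold higher. The genotype differences of Cyp1a1 were -3.46 without infection and 0.43 with it. The hormone gene Oxt was 14.7-fold higher. The 4 genes ranked next were at 2.66 to 3.19. The IL-17 response list had a median of 0.75 (percentile 100), with 8 of 20 members at least 2-fold higher and 1 lower. Ccl20 was at 2.19, Saa2 at 2.63, Nos2 at 1.87 and Duoxa2 at 1.59, while the lectin gene Mbl2 was at -1.38. The IL-17 and Th17 cytokine list was at 0.26 (percentile 99.7), with the chemokine receptor gene Ccr6 at 1.73, but at -0.35 among brighter probes. The type 2 cytokine and tuft cell list was at -0.004 (percentile 40.9), with 0 of 19 members at least 2-fold higher and 0 lower. Trpm5, Dclk1 and Il4 were at -0.01, -0.18 and 0.40. Eosinophil genes were at 0.21 (percentile 96.5), with Siglecf at 0.07, and mast cell genes were at -0.03 (percentile 31.0).

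The lowest gene on this infected array was Bco1, 47.5-fold lower. The heat shock gene Hspa1a was 7.84-fold lower, and its other probes were at -2.98 to -2.87. Cyp2e1 was at -2.58, the metallothionein gene Mt2 at -2.52, Cyp27a1 at -2.01, Slc7a14 at -1.89 and Car3 at -1.86. The following 4 genes were at -1.84 to -1.68. Adipose genes had a median of -1.24 (percentile 0), with 8 of 14 members at least 2-fold lower, among them Adipoq at -1.82 and Plin1 at -1.37. Type I interferon-stimulated genes were at -0.46 and interferon-gamma response genes at -0.30 (percentile 0 for both). Of their members, 0 of 26 and 0 of 27 were at least 2-fold lower, and 1 interferon-gamma response gene was at least 2-fold higher. Usp18 was at -0.97 and Gbp6 at -0.94. Smooth muscle genes were at -0.39 and clock genes at -0.38 (percentile 0 for both), with Hlf at -1.37. Goblet cell genes were at -0.08 as a median and 0.04 as a mean. Xenobiotic metabolism genes were at 0.05 (percentile 75.3). Pla2g1b was at least 7.23-fold lower. In all, 17 of 38 lists were outside the central 95% of random lists. The total of 400 genes was 199 with normexp background correction, 210 on the authors' scaled table, 101 among brighter probes and 1317 with no background filter.

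Both infection responses shared part of their genes. Over 18587 genes well above background on all arrays, the log2 differences correlated with r of 0.33 and rho of 0.26. In both, 71 genes were at least 2-fold higher, against 5.31 if the responses were independent, and 36 were at least 2-fold lower, against 1.63. Shared higher genes included Retnlb at 6.47 and 2.62, Saa2 at 4.80 and 2.63, Gml at 4.01 and 2.28, B3galt5 at 3.95 and 1.90 and Lrg1 at 2.98 and 1.73 on the WT arrays and the arrays labelled IL-17RA-deficient. Shared lower genes included Bco1 at -4.64 and -5.57, Cubn at -4.81 and -1.63, Cyp3a11 at -2.80 and -1.12 and Pdk4 at -2.71 and -1.68. They also included the clock gene Hlf at -2.47 and -1.37, Msln at -1.70 and -1.51 and Upk3b at -1.36 and -1.79. Clock genes as a list were at -0.83 and -0.38 and adipose genes at -0.34 and -1.24. Whether infection accounts for the whole overlap was not tested. Across all genes, r was 0.18 with no background filter.

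**Figure D2:**
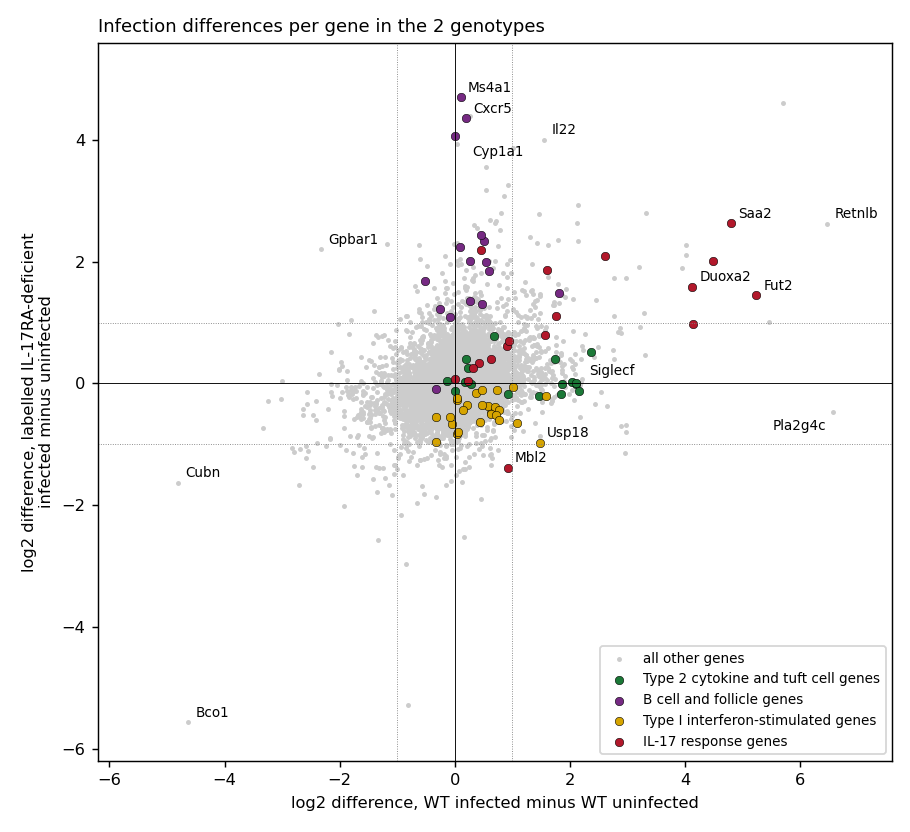
Log2 difference between infected and uninfected arrays for each gene, on the WT arrays (horizontal) and the arrays labelled IL-17RA-deficient (vertical), with 4 gene lists coloured and dotted lines at 2-fold. Tuft cell genes lie to the right at vertical values near 0, B cell genes lie high at horizontal values near 0, and Defcr-rs2, at -11.06 on the WT arrays, lies outside the plotted range.

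The difference between the infection responses, deficient minus WT, addresses which genes responded unlike each other by label. It was at least 2-fold for 758 genes, higher for 414 and lower for 344, and it was not tested. The Defcr-rs2 difference was 10.82, a rough value because its signal was near background on every array but WT uninfected. The B cell genes Ms4a1, Cxcr5, Fcmr and Tnfrsf13c were at 4.60, 4.15, 4.06 and 3.02, and the bile acid receptor gene Gpbar1 was at 4.53. Cyp1a1, Igkv12-38, Cubn, Acp6, Lamb3 and Olfr165 were at 3.90, 3.48, 3.18, 3.04, 3.0 and 2.95. At the lower end, Pla2g4c was at -7.04, Retnla at -4.10, Retnlb at -3.84, Fut2 at -3.79 and Saa3 at -3.16. The other probe of Fut2 was at -1.91. The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc, whose sequences are alike, were at -3.77, -3.65 and -3.57. Mod1 and Me1, both names of malic enzyme, were at -3.01 and -2.76, Kcnj16 at -2.85 and Pnliprp2 at -2.72.

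Gene lists differed between the responses in the same way. The list median was -1.34 for type 2 cytokine and tuft cell genes, -1.31 for eosinophil genes, -0.83 for mast cell genes and -0.52 for IL-17 response genes (percentile 0 for each). B cell and follicle genes were at 1.69, xenobiotic metabolism genes at 1.01 and T cell and cytotoxic lymphocyte genes at 0.63 (percentile 100 for each). Clock genes were at 0.40, with Dbp at 1.94 and Per2 at 1.39, adipose genes at -0.57 and smooth muscle genes at -0.62. In total 23 lists were outside the central 95% of random lists. Only 5 genes were at least 2-fold in opposite directions: Retnla, Aldh1a1, Igkv12-38, Gpbar1 and 4930567H12Rik, the last at -1.40 on the WT arrays and 1.18 on the others. The last was named after its values were seen. The total of 758 genes was 420 with normexp background correction, 422 on the authors' scaled table, 239 among brighter probes and 2486 with no background filter.

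The uninfected genotype comparison asks what differed without infection. Interferon-stimulated genes were higher on the array labelled IL-17RA-deficient, and IL-17 response genes and mast cell genes were lower. Of 18964 measured genes, 102 were at least 2-fold higher and 194 at least 2-fold lower, with bounds for 44 and 54 more. Mbl2, which encodes the complement-activating mannose-binding lectin C, was 24.5-fold lower. The interferon-induced gene Ifi44 was 4.60-fold higher, with its other probe at 2.64.

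IL-17 response genes had a median of -0.58 (percentile 0), with 6 of 19 members at least 2-fold lower and 0 higher. Duoxa2 was at -1.34, Zc3h12a at -1.30, the IL-17 signalling factor gene Nfkbiz at -1.19 and Pigr at -1.02. Type I interferon-stimulated genes were at 0.95 (percentile 100), with 12 of 26 members at least 2-fold higher, including Oas2 at 1.53, Mx2 at 1.52 and Usp18 at 1.48. Interferon-gamma response genes were at 0.76 (percentile 100), with 8 of 27 members at least 2-fold higher, including Ifng at 1.48, Irgm1 at 1.28 and Igtp at 1.27. T cell and cytotoxic lymphocyte genes were at 0.39, adipose genes at 0.39 and proliferation genes at 0.26 (percentile 100 for each). Mast cell genes were at -0.71, with Mcpt1 at -1.24. Paneth cell genes other than alpha-defensins were at -0.37, type 2 cytokine and tuft cell genes at -0.36 and xenobiotic metabolism genes at -0.30 (percentile 0 for each). Blood genes were at -0.33, with Hba-a1 at -0.99. Complement and lectin genes were at 0.14 as a median (percentile 99.7) and -0.11 as a mean, and clock genes were at -0.01 (percentile 40.1). Nnt, which differs between mouse strains, was at 0.91.

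The 5 highest genes with a symbol were Slc7a14 at 2.62, Mt2 at 2.26, Inip at 2.24, Ifi44 at 2.20 and Rasd1 at 1.93, and the other probe of Inip was at -0.10. The following 7 genes were at 1.55 to 1.88. Of these, Wdfy1 was at 1.88 with other probes at -0.99 and 1.57, and Vsig2 at 1.82 with its other probe at -0.11. The lowest was Defcr-rs2, 2153-fold lower, a rough value because its signal on the array labelled IL-17RA-deficient uninfected was near background. Then came the C-type lectin gene Clec1b, 30.3-fold lower, Mbl2, the immunoglobulin gene Igkv12-38, 22.8-fold lower, and Csta2, 17.0-fold lower. The next 7 were at -4.03 to -2.37. Defcr-rs10 was at least 2370-fold lower, Cstdc6 at least 10.8-fold lower and Pla2g1b at least 7.6-fold higher. Here 19 lists were outside the central 95% of random lists. The total of 296 genes was 166 with normexp background correction, 165 on the authors' scaled table, 116 among brighter probes and 1202 with no background filter.

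The infected genotype comparison asks what differed between the infected mice. Type 2, tuft cell, eosinophil, mast cell and IL-17 response genes were lower on the array labelled IL-17RA-deficient, and B cell and T cell genes were higher. Of 18871 measured genes, 323 were at least 2-fold higher and 382 at least 2-fold lower, with bounds for 81 and 97 more. Pla2g4c was 344-fold lower and Mbl2 120.4-fold lower, while Ms4a1 was 36.6-fold higher.

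IL-17 response genes had a median of -1.10 (percentile 0), with 12 of 21 members at least 2-fold lower and 1 higher. Duoxa2 was at -3.87, Fut2 at -3.48, Saa1 at -3.05 and Zc3h12a at -2.06, and Ccl20 was at 1.30. The type 2 cytokine and tuft cell list was at -1.71 (percentile 0), with 10 of 18 members at least 2-fold lower and 0 higher, such as Sucnr1 at -3.52, Alox5 at -3.48 and Trpm5 at -3.17. Eosinophil genes were at -1.50 (percentile 0), with Siglecf at -3.15, and mast cell genes at -0.98 (percentile 0), with Mcpt2 at -2.91 and Cpa3 at -2.43. Paneth cell genes other than alpha-defensins were at -0.89 and goblet cell genes at -0.42 (percentile 0 for both), with Ang4 at -1.87 and Muc4 at -4.01. Muc4 was already at -2.57 in the uninfected genotype comparison.

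B cell and follicle genes were at 1.78 (percentile 100), with 17 of 20 members at least 2-fold higher and 0 lower. Cxcr5 was 26.4-fold higher, Fcmr 25.0-fold higher, Cxcl13, the chemokine that attracts CXCR5-bearing cells, 10.6-fold higher, and Pax5 at least 20.7-fold higher. T cell and cytotoxic lymphocyte genes were at 0.98 (percentile 100), with 10 of 22 members at least 2-fold higher, including Cd7 at 1.46 and Gzma at 1.17. MHC class II genes were at 0.62 (percentile 100). Xenobiotic metabolism genes were at 0.45 and clock genes at 0.45 (percentile 100 for both), with Cyp2b10 at 2.17 and Dbp at 1.67. Smooth muscle genes were at -0.56 and adipose genes at -0.35, while blood genes were at -0.04. Type I interferon-stimulated genes were at 0.06 (percentile 81.2), and interferon-gamma response genes at 0.42 (percentile 100).

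After Ms4a1, Cxcr5 and Fcmr, the highest genes were the laminin gene Lamb3 at 3.72 and Cxcl13 at 3.41, and the next 7 were at 2.79 to 3.35. After Pla2g4c and Mbl2, the lowest were Csta2 at -5.14, Gsdmc2 at -4.45 and Gsdmc at -4.39, and the next 7 were at -4.37 to -3.72. Itprid1 was at least 15.6-fold lower, and Fgf15, the gut hormone of bile acid control, was at least 8.2-fold lower. In this comparison 22 lists were outside the central 95% of random lists. The genotype differences with and without infection correlated across genes with r of 0.33 and rho of 0.27, and shared 17 genes at least 2-fold higher and 66 lower, against 1.61 and 3.57 if independent. The total of 705 genes was 391 with normexp background correction, 405 on the authors' scaled table, 235 among brighter probes and 1810 with no background filter.

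**Figure D3:**
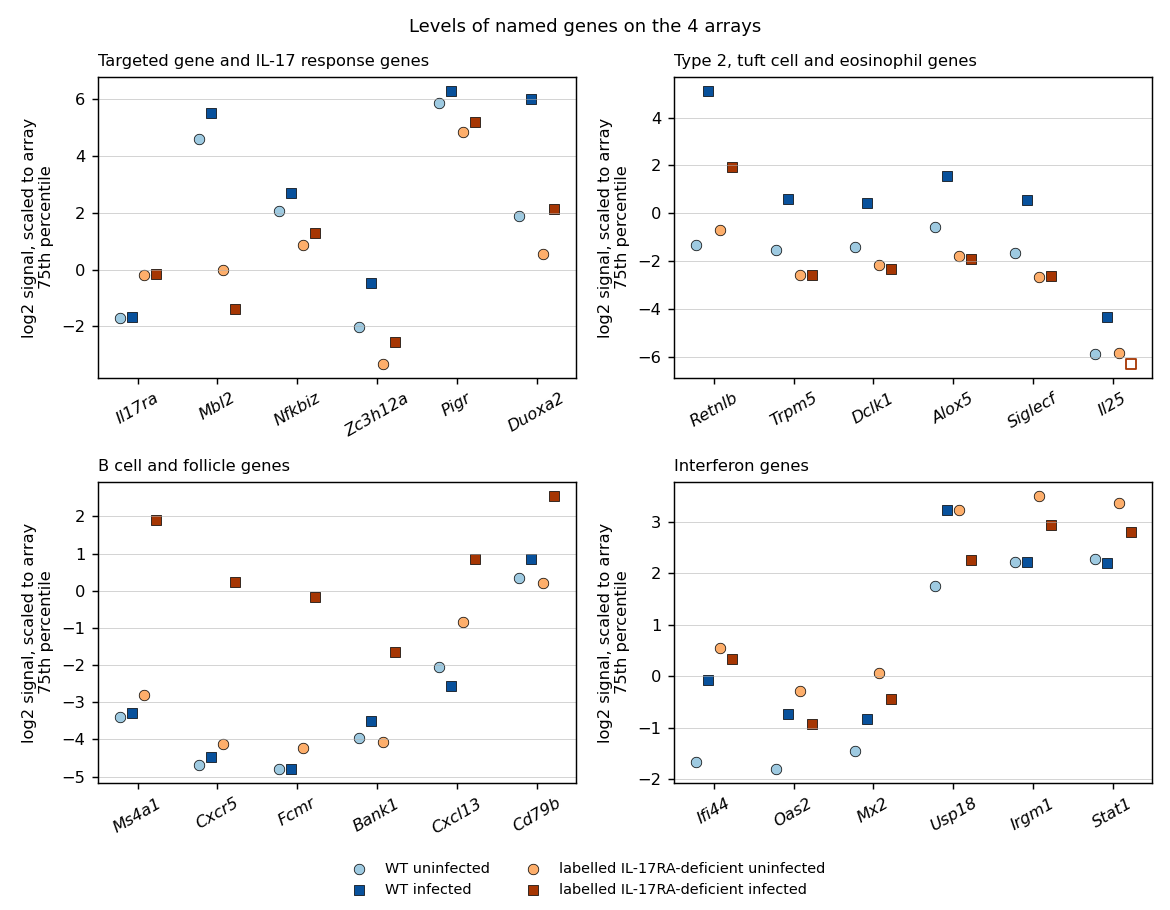
Log2 signal, scaled to each array's 75th percentile, of 24 named genes on the 4 arrays, with circles for uninfected, squares for infected, blue for WT and orange for the arrays labelled IL-17RA-deficient, and open symbols for signals not well above background. Mbl2 reads 4.60 and 5.51 on the WT arrays and -0.02 and -1.40 on the others, and Ms4a1 reads 1.91 on the array labelled IL-17RA-deficient infected and -3.39 to -2.79 elsewhere.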

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

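No explanation was tested for the results in this part, and none of these differences between the infection responses was tested, since each group is 1 array. They stand out because the infected minus uninfected difference had 1 sign on the WT arrays and the opposite sign on the arrays labelled IL-17RA-deficient. Type I interferon-stimulated genes had medians of 0.48 and -0.46, a difference of -0.86. Their genotype difference was 0.95 without infection and 0.06 with it, so the genotypes differed mostly on the uninfected arrays. Smooth muscle genes had medians of 0.23 and -0.39, a difference of -0.62. Goblet cell genes had medians of 0.24 and -0.08, and the median of the member differences was -0.31, but as a list mean the deficient response was 0.04, so its sign rests on the median. Retnla, a gene induced by IL-4 and IL-13, was at 2.96 and -1.14, a difference of -4.10. Aldh1a1, which makes retinoic acid, was at -1.81 and 1.03, a difference of 2.85. The immunoglobulin gene Igkv12-38 was at -1.18 and 2.30, a difference of 3.48, and its genotype difference was -4.51 without infection and -1.03 with it. The bile acid receptor gene Gpbar1 was at -2.32 and 2.21, a difference of 4.53.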

How the results depend on the processing

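List values without the floor on dim signals, and the window around Il17ra without bounds, were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each group is 1 array. In the order WT infection, deficient infection, uninfected genotype, infected genotype and difference of responses, gene counts were 407, 199, 166, 391 and 420 with normexp, 418, 210, 165, 405 and 422 on the authors' scaled table, and 265, 101, 116, 235 and 239 among brighter probes. They were 1677, 1317, 1202, 1810 and 2486 with no background filter, 1902, 1263, 1004, 2065 and 2293 at 1.5-fold, and 231, 123, 63, 255 and 237 at 3-fold. A looser or stricter filter or threshold changes the genes counted by construction; for normexp and the authors' table the cause was not tested. Quantile, array median and loess scaling, the mean over probes and the filter on all 4 arrays kept each count within 1.5 times. The correlation of the responses was 0.352 with normexp, 0.351 on the authors' table, 0.314 with the mean over probes, 0.392 among brighter probes and 0.184 with no filter, and the cause was not tested. The uninfected Il17ra difference was 1.286 on the authors' table and between 1.29 and 1.54 over all alternatives. Signs turned for Cyp3a44 (-0.155, difference of responses) and Hspb1 (0.276, deficient infection) with the mean over probes. Among brighter probes they turned for IL-17 and Th17 cytokines (-0.217 in WT and -0.350 in deficient infection), B cell and follicle genes (-0.078) and enteric neuron genes (0.027), both in WT. As list means they turned for goblet cell genes (0.043, deficient infection) and complement genes (-0.106, uninfected genotype). The cause was not tested. Of 4708 alternative values for 554 named gene results, 4033 were within error, 673 moved and 2 turned sign. In every alternative that kept them, 423 results were at least 2-fold. The background and brightness filters cannot change a gene's value, and genes failing a filter were left out under it. These totals therefore overstate how stable the named genes are. Lists outside the central 95% numbered 22 to 28, 15 to 18, 14 to 23, 20 to 24 and 20 to 24, and 83 of 108 such lists stayed outside in every alternative. Dim signals limit the counts, since 68.5% to 69.2% of spots were well above background.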

Other observations

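The tests of swapped labels, of a transcript holding the probed end, of blood, of faulty spots and of Paneth cell number were chosen only after the result was seen, as were the window around Il17ra and the lists of lymphoid tissue and germinal centre genes.

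Within 10 Mb of Il17ra on chromosome 6, 11 of 252 genes (4.37%) were at least 2-fold in the same direction in both genotype comparisons with dim signals set at their bound, and 2 of 236 other windows were as high, overlapping ones on chromosome 16 with up to 6.98%. Of the 11, 8 lay together 8.14 to 9.53 Mb from Il17ra, in a stretch holding related lectin genes, and within 5 Mb there were 3 of 148 (2.03%). Among genes well above background on all 4 arrays, 7 of 229 (3.06%) were, and 2 of 232 other windows, both on chromosome 16, were as high. These were Klrb1c at -2.01 and -1.12, Klra17 at 1.61 and 1.63, Clec1b at -4.92 and -3.17, Clec2d at 1.54 and 1.68, BC064078 at 3.47 and 3.40, Dppa3 at -1.82 and -1.40 and the tuft cell gene Alox5 at -1.21 and -3.48 in the uninfected and infected comparisons. The list of neighbours of Il17ra fixed before the data had medians of 0.11 (percentile 95.4) and -0.07 (percentile 18.4), both inside the range of random lists. The Klra genes resemble each other, so their probes can share signal.

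Il17ra was higher on both arrays labelled IL-17RA-deficient. Swapped genotype labels were tested on IL-17 response genes, which would then be higher on those arrays. Their medians were -1.10 with infection (percentile 0) and -0.58 without, which argues against a swap. The argument is limited, because these genes rose with infection under both labels, by medians of 1.56 (WT) and 0.75. Their level therefore does not depend on IL-17RA alone. A transcript of the disrupted gene that keeps the probed end may give the signal, but the 2 probes span only 197 bases and so this cannot be told from other sources. A biological difference in Il17ra expression was not tested.

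B cell and follicle genes were higher on the array labelled IL-17RA-deficient infected, by a median of 1.78 against WT infected. More blood in that pool is argued against there by the median of Hba-a1, Hbb-bt and Alas2, 0.10. Against the array labelled IL-17RA-deficient uninfected these were at 1.33, below the B cell median of 1.93. Between the uninfected arrays the lists went opposite ways, with blood genes at -0.33 and B cell and follicle genes at 0.23. Blood therefore stays open for the deficient infected pool against the deficient uninfected pool, as a source of part of the difference. The hypothesis that the pool held more organised lymphoid tissue was tested, with its prediction written before, on 10 genes of lymphoid tissue stroma, vessels and epithelium in no other list, of which 7 were on the array; their median was 0.73 (percentile 100), with 4 of the 7 above 0 and 2 at least 2-fold higher, Mfge8 at 1.19, Ccl19 at 1.67 and Marcksl1 at -0.43. The 7 germinal centre genes were at 0.65, with 2 at least 2-fold higher and 1 lower, Il4i1 at 1.83 and Rgs13 at -2.56 among them. More lymphoid tissue may account for part of the pattern, and whether it came from dissection, infection or genotype stays open and untested.

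Defcr-rs2 and Defcr-rs10 were near background on every array but WT uninfected. Faulty spots are argued against, since 3 probes at separate places each differed, the smallest gap to the highest other array being 11.06 on the log2 scale. Fewer Paneth cells in the WT infected pool is argued against by the other 11 alpha-defensin genes, with a median of 0.07 and a range of -0.40 to 0.26, and by Lyz1 at -0.08. A genetic difference between the pooled mice may be a candidate explanation and was not tested, and whether the WT uninfected mice came from another colony is not given in the sources used here. If they did, the WT infection and uninfected genotype values and the difference of the responses, 10.82 for Defcr-rs2, would mix colony with infection or genotype for other genes too.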
